A study of Mus musculus with 5 samples.

How the data were processed

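A total of 5 one-colour arrays were analysed, 3 of P19C6 cells at 0 hour and 2 after 4 days in N2B27. Per the labels, total RNA was extracted and labelled by PCR with a Cy5 primer. Per the file headers, the authors quantified 1 Cy5 image per array with a fixed circle, without correction for crosstalk or subtraction of background. Each deposited scanner file gives the intensity of every spot and of its local background on a linear scale that ends at 65535. The deposited value table of the series holds an intensity per spot that equals spot minus local background in each scanner file, to within 5e-06, so that it carries no log, scaling or centring. Its medians over all spots were 496, 655 and 499 for the 0 hour arrays and 484 and 368 for the 4 day arrays. The image analysis program, the probe sequences and the microRNA behind each code are not given in the sources used here.

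Groups and replicate numbers came from the labels' titles. The titles number the library 1 on every 0 hour array and 2 on every 4 day array, whereas the series text speaks of 2 libraries per sample and 2 hybridisations per library. Arrays were taken as the samples. No 2 arrays shared an intensity below the ceiling at any spot. The file headers give replicates 1 of both groups a common run name, and likewise replicates 2, so the numbers mark shared runs. The deviations from the group means do not settle whether a run left a mark. They correlated at 0.38 across features for the arrays numbered 1 and at 0.15 for those numbered 2, but the third 0 hour array, from a run of its own, correlated at 0.25 with replicate 2 of the 4 day group, and with 2 arrays in that group the deviations of one mirror those of the other.

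Spot intensities were corrected with normexp and an offset of 50 on all spots, put on the log2 scale and quantile normalized over the 1218 spots with an M code. Spots that the files mark to be ignored were left out, 3 of them microRNA spots on replicate 2 of the 4 day group. The reading of that mark, as 0 for ignored, rests on its column name. The 3 spots of a feature were averaged. The floor of an array was the mean plus 2 SD of the intensities of its 12 spots with a B code, after subtraction of local background. The meaning of that code is not given in the sources used here, and it was chosen for its low signal on every array. A feature was tested if it was above the floor on at least 2 arrays, which left 323 of 406. No name carried a species, so every M code counted as a microRNA feature. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 3 residual and 4.04 prior degrees of freedom) and the Benjamini-Hochberg adjustment over the tested features, at an adjusted p of 0.05. Where a bright feature was at the scanner ceiling, the fitted fold is given as limited by it. Where one group was at or under the floor on all its arrays, the bound sets the mean of the other group against, per array, the higher of the feature's own value and the lowest value of a feature above the floor. Figures were drawn with matplotlib 3.10.9.

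The design, the alternatives and the rule for the features to be named were set before the data were examined, except for the choice of the B code for the floor and 4 added alternatives. The rule took the largest changes in each direction among features past the threshold whose arrays did not overlap and that were above the floor on every array of the brighter group. It met 86 rises and 53 falls, and since the codes are not paired with names, only the first 2 each way are printed. For the same reason, 16 lists of microRNAs fixed in advance could not be applied, and no test of a list was run. The steps were tested on simulated data for the comparison of 4 day against 0 hour, with 20 draws per setting. Levels were the 0 hour means of the 406 features, and all features were given a common typical spread rather than their own. The changed features were drawn only from the brighter ones, so the recovered percentages hold for those. The simulated features lay higher over the floor than the real ones, since 399.6 to 400.8 of 406 were tested on average against 323 in the data, so that the percentages show how the steps behave and are not error rates of the main comparison. With no change, 0.10 features were called per draw on average. With 50 rises and 50 falls of 2-fold, 89.2% were recovered and 4.65% of the calls were false. With 20 rises and 20 falls of 4-fold, 98.6% were recovered and 10.8% were false. With 50 of each at 4-fold, 98.4% were recovered and 20.8% were false, and with 70 rises and 30 falls of 4-fold, 97.1% were recovered and 31.7% were false. The median estimate was then 1.47 for a true log2 fold change of 2. Alternatives covered the background correction, the scaling, the filter, the spot summary, the variance model, the replicate block and each array left out.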

Results

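MicroRNA levels were measured in P19C6 cells, a clone of the mouse embryonal carcinoma line P19, before and after neural differentiation in N2B27, a serum-free medium. Small RNA was amplified and labelled with the dye Cy5, and each labelled sample was hybridised alone to a spotted array. There were 3 arrays of undifferentiated cells at 0 hour and 2 arrays of cells after 4 days in N2B27. Each array held 1296 spots, 3 for each feature, and 406 features carried a microRNA code (M1 to M406). The median intensity of the 406 microRNA features, after subtraction of local background, was 493, 652 and 493 on the 0 hour arrays and 508 and 382 on the 4 day arrays. The replicate spots of a feature had a median coefficient of variation of 10.8 to 12.8% per array. The number of arrays, 3 against 2, limits the precision of every comparison. The labels number the library 1 on all 0 hour arrays and 2 on all 4 day arrays, while the series text describes 2 libraries per sample. Every limma p-value given here therefore measures the spread between arrays, which may be technical only. If the titles hold, library and day also changed together. A difference between the groups could then not be told apart from one between 2 libraries. The features are reported by code because the tables used here do not pair a code with a microRNA, and no genomic position is given for the same reason.

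The first question was how alike the arrays of a group were. Arrays of the same group had closely similar microRNA profiles, and arrays of different groups did not. Over the 323 tested features, the Pearson correlation of normalized log2 values between arrays of the same group was at least 0.93, and between groups it lay between 0.75 and 0.79. The corresponding Spearman correlations were at least 0.88 within a group and between 0.73 and 0.80 across groups. These correlations run across features, which are not independent replicates. The median SD of a feature was 0.29 on the log2 scale over the 3 arrays of undifferentiated cells and 0.16 over the 2 arrays of differentiated cells.

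Of the 406 microRNA features, 195 were above the floor on all 3 arrays of undifferentiated cells and 291 on both arrays of differentiated cells. A total of 191 were above it on all 5 arrays, and 41 were above it on none. Only 4 features were above the floor on every 0 hour array and on neither 4 day array, whereas 18 were above it on both 4 day arrays and on no 0 hour array. The floor itself, the mean plus 2 SD of the spots with a B code, was 461, 433 and 440 at 0 hour and 242 and 136 at 4 days, and 3 arrays had to pass in one group but 2 in the other. The 2 counts are therefore not a like-for-like comparison of how many microRNAs the cells made. When a feature had to pass on only 1 array of its group, 325 were detected at 0 hour and 337 at 4 days.

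The main comparison asked which microRNAs differed between cells after 4 days of neural induction and undifferentiated cells. A large part of the measured microRNA profile differed between the arrays of the groups. Of 323 features tested, 145 passed an adjusted p of 0.05 (limma, two-sided, Benjamini-Hochberg), 86 higher and 59 lower at 4 days, and 178 did not pass. In simulated data with 50 rises and 50 falls of 4-fold, 20.8% of the calls were false. That setting differed from the data, but the share of false calls here may also be higher than the threshold implies. The median log2 fold change was 1.13 among the features that rose and -1.66 among those that fell. The fitted change was 2-fold or more for 55 of the features that rose, 4-fold or more for 12 and 8-fold or more for 5. It was 2-fold or more for 48 of those that fell, 4-fold or more for 23 and 8-fold or more for 9. These fits include features whose dimmer group lay wholly under the floor. With the lower bound in place of the fit for those, or no change where there is none, 49 rose and 46 fell by 2-fold or more, the counts at 4-fold and 8-fold stayed as they were, and the medians were 1.06 and -1.66. In all 145 called features, the arrays of the groups did not overlap. Such separation was found in 61.9% of the tested features, against 20% expected when 5 arrays are grouped at random. The 20% is an average over groupings. Any difference shared by the arrays of a group, technical or not, would also raise the share. The number of called features was 90 without replicate 1 of the 4 day group and 73 without its replicate 2, since 1 array then stood for the group and the 0 hour arrays alone gave the spread. With that limit, 69 features were called in the same direction whichever array was left out.

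**Figure D1:**
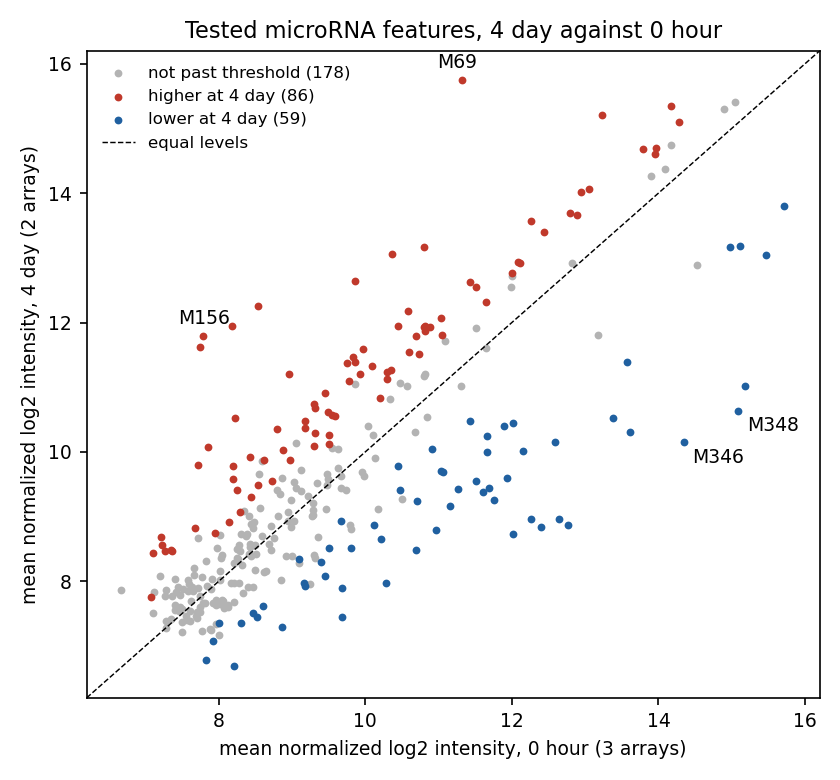
Mean normalized log2 intensity of each of the 323 tested microRNA features at 0 hour (x axis, 3 arrays) and at 4 days (y axis, 2 arrays). The 86 features called higher (red) and the 59 called lower (blue) lie on either side of the dashed line of equal levels, and grey points did not pass the threshold.

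The split between rises and falls depended on how the arrays were scaled to each other. With quantile normalization 59.3% of the called features were higher, and the median log2 fold change of all tested features was 0.15. With no normalization between arrays, 102 were higher and 48 lower, and all 150 had a fitted change of 2-fold or more. The adjusted p of M69 was then 2.41e-25 (limma), against 0.000118 in the main setting. The spread used by the test thus differed as well as the scaling. Scaling to the median gave 73 higher and 106 lower, with a median log2 fold change of -0.41. Scaling to the 75th percentile gave 68 higher and 120 lower, with a median of -0.49. Cyclic loess gave 59 higher and 65 lower, and scaling to the features with a P code gave 49 higher and 151 lower, with a median of -0.63. All fold changes are therefore relative to the scaling of the arrays. Across the 6 scalings, 82 features were called the same way each time, 38 of them higher and 44 lower, and no feature was called in opposite directions.

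**Figure D2:**
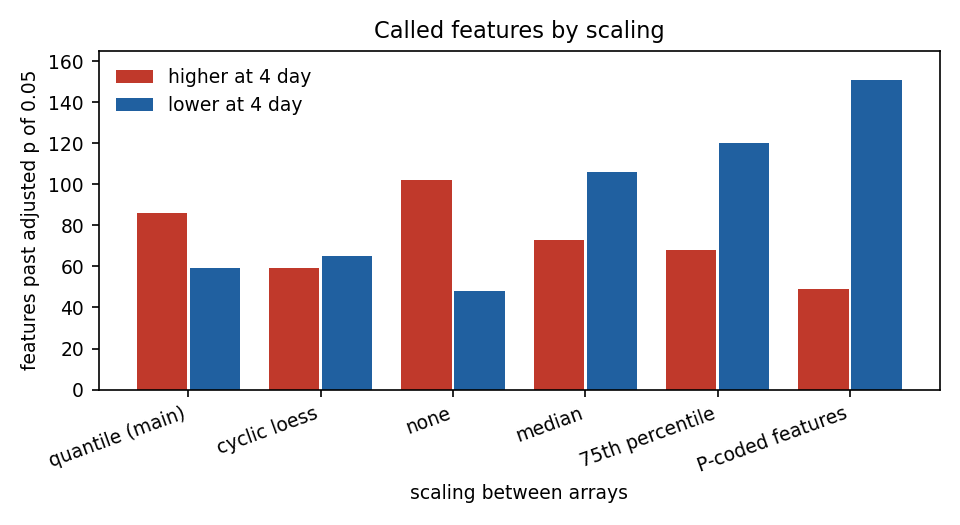
Number of microRNA features past an adjusted p of 0.05 (y axis, limma) in each direction under 6 ways of scaling the arrays (x axis). The features called higher range from 49 to 102 and those called lower from 48 to 151.

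The 2 features with the largest fitted rise and the 2 with the largest fitted fall in the main setting are described here, and their ranks were not compared across settings. M69 rose from a normalized log2 intensity of 11.32 ± 0.63 (SD, n = 3 arrays) to 15.74, which was the top of the scale on both 4 day arrays. Its intensity was 2454 ± 1026 at 0 hour (SD, n = 3 arrays), while at 4 days it was 64806 and 64914, with 1 of its 3 spots at the scanner ceiling of 65535 on each array. Under quantile normalization its fitted rise, which the ceiling limits, was 21.4-fold (log2 fold change 4.42, SE 0.36, limma adjusted p = 0.000118). Because both 4 day values lay at the top of the scale, they added almost no spread to the SE. The fit also varied with the setting, as the log2 fold change was 4.10 without replicate 3 of the 0 hour group and 3.92 with cyclic loess. M156 rose from 7.79 ± 0.10 to 11.79 ± 0.10 on the log2 scale (log2 fold change 4.00, SE 0.20, limma adjusted p = 2.21e-05). At 0 hour M156 was above the floor on 1 of the 3 arrays, so that its starting level lay at the limit of measurement and the size of its rise is uncertain. Without background correction the log2 fold change was 3.45.

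In undifferentiated cells M348 had an intensity of 30210 ± 10668 (SD, n = 3 arrays). At 4 days its intensity was 2212 and 2208. Under quantile normalization M348 fell 21.8-fold, from 15.09 ± 0.26 to 10.64 ± 0.14 on the log2 scale (log2 fold change -4.45, SE 0.24, limma adjusted p = 2.21e-05). M346 fell 18.3-fold under the same normalization, from 14.35 ± 0.19 to 10.16 ± 0.04 (log2 fold change -4.19, SE 0.21, limma adjusted p = 2.21e-05). Its intensity was 18779 ± 7518 at 0 hour (SD, n = 3 arrays) and 1466 and 1694 at 4 days. Without normalization between arrays the log2 fold change was -3.73 for M348 and -3.52 for M346. Both features stayed above the floor on both 4 day arrays. Each of the 4 named features was called in the same direction under all 6 scalings.

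**Figure D3:**
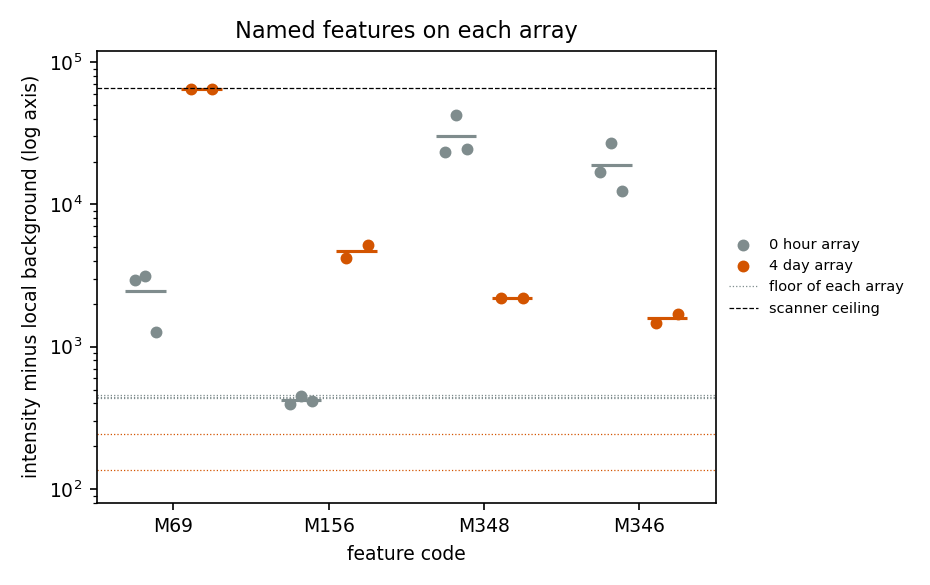
Intensity minus local background (y axis, log scale) of the 4 named microRNA features (x axis) on each 0 hour array (grey points) and 4 day array (orange points), with group means as bars, the floor of each array as dotted lines and the scanner ceiling of 65535 as a dashed line. M69 lies at the ceiling at 4 days, and M156 lies near the floor at 0 hour.

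Some of the called changes can only be bounded, because one state gave no signal above the floor. Of the 86 features that rose, 7 were at or under the floor on all 3 arrays of undifferentiated cells. In the main setting, with quantile normalization, the rise was at least 1.43 to 1.70-fold for 6 of them, and for the other 1 no fold can be given. Of the 59 features that fell, 6 were at or under the floor on both arrays of differentiated cells. The 4 of these that were above the floor on all 3 arrays of undifferentiated cells were at least 1.73 to 4.60-fold lower after 4 days, and the other 2, above it on 2 of the 3 arrays, were given no bound. The bounds were not computed under the other scalings. They hold for quantile normalization only, as the median log2 fold change of all tested features ranged from -0.63 to 0.21 over the 6 scalings.

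The headers of the scanner files place replicate 1 of both groups in one run and replicate 2 of both groups in another, with the third 0 hour array in a run of its own. The change was therefore also read within each of the 2 shared runs, where 1 array stands for each group and no test is possible. By the titles, both runs hold library 1 at 0 hour and library 2 at 4 days, so their agreement may be technical only. The log2 differences of the 2 runs correlated across the 323 features with a Pearson r of 0.93 and a Spearman rho of 0.88, and 276 features had the same sign in both. All 145 called features had the same sign in both runs, although they were chosen on these arrays. The features that rose had a median log2 difference of 1.12 in the first run and 1.11 in the second, and those that fell had -1.79 and -1.68. M348 differed by -4.09 and -4.56, and M346 by -4.39 and -4.20. The values for M69, 3.82 and 4.37, are limited by the ceiling. Those for M156, 3.87 and 4.19, are uncertain because it was under the floor on the 0 hour array of the first run. With the replicate number as a block, 173 features passed (limma, adjusted p under 0.05), 99 higher and 74 lower. The third 0 hour array, alone in its run, adds nothing to the comparison of the groups under that block. The fit thus rests on the 2 shared runs and has fewer residual degrees of freedom than the main one.

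The features outside the microRNA codes gave the background and the bright end of each array. The files do not say what their letters stand for. All 4 features with a B code and 10 of the 14 with an N code were dimmer on both 4 day arrays than on every 0 hour array, and the median ratio of 4 day to 0 hour intensity was 0.46 for B and 0.50 for N. In contrast, 7 of the 8 features with a P code were brighter on both 4 day arrays, with a median ratio of 1.71. The dim and the bright ends of the arrays thus lay further apart at 4 days. These ratios were taken before any scaling and were not tested.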

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

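The tests of N14 against the other dim features and against the microRNA features were chosen only after its values were seen, and the test of touching features was set before its result was seen.

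A total of 8 features outside the microRNA codes stood out because they were brighter on both 4 day arrays than on every 0 hour array, in a part of the array that the main comparison does not use. One of them carries an N code and 7 carry a P code. N14 had an intensity of 396, 789 and 406 on the 0 hour arrays and of 2823 and 3394 on the 4 day arrays, a ratio of 5.86 between the group means. It was above the floor on 1 of the 3 arrays at 0 hour, and with the values under the floor raised to it the ratio was at least 5.52. Among the P codes the ratio was 1.76 for P10E, 1.75 for P10S, 2.05 for P15E, 1.76 for P15S, 1.62 for P20S, 1.55 for P25S and 1.66 for P5E.

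N14 was weighed further, as a member of a set of features that are otherwise mostly dim. A brighter scan of the 4 day arrays would raise the other N and B features too. It was ruled out as the whole cause, because the log2 ratio of N14 lay 3.61 above the median of the 17 others, whose SD was 0.26, and 0 of the 17 had a ratio above 1. Most of those features lie near the floor, but the 191 microRNA features above it on all 5 arrays had a median ratio of only 1.27 before any scaling. Of these 191, 5 had a ratio of 5.52 or more, the N14 ratio with its values raised to the floor, so a rise of that size was not confined to N14. Carry-over from touching features was also excluded, since 0 of the 5 features touching N14 was as bright on both 4 day arrays and had risen as much, and the 3 spots of N14 were alike on each of those arrays (2682 to 3082 and 2994 to 3680). On replicate 2 of the 0 hour group the spots ran from 474 to 1273, so that its level there rests on uneven spots. An RNA that the probe matches and that differs between the states may account for the change, but which RNA that would be was not tested, since the code is not explained.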

How the results depend on the processing

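Scaling to the P-coded features, the 2 other sources of the floor and the block on 4 arrays were chosen after seeing the data. The total of 145 called features stayed within 1.5 times that number under every alternative except leaving out a 4 day array. Leaving out 1 array gave 73 to 160 calls, 37 to 93 higher and 36 to 67 lower, the lowest with a single 4 day array (replicate 1) left. Features called higher numbered 49 with scaling to the P-coded features. Features called lower numbered 106 with scaling to the median, 120 with the 75th percentile, 151 with the P-coded features and 107 with the deposited value table on log2. No main call was past the threshold in the opposite direction under any alternative. The 103 fitted changes of 2-fold or more became 166 with the deposited value table. With the replicate number as a block, 173 features were called on 5 arrays and 185 on the 4 arrays of the shared runs, and 144 of the 145 main calls were kept in the first. Both fits compare the groups within the same shared runs, so neither stands apart from the other. The 4 named features kept their direction and stayed past the threshold in every alternative in which they were tested, with an adjusted p of at most 0.00174 (limma). M69 ranged from 3.92 to 4.97 on the log2 scale, M156 from 3.39 to 4.24, M348 from -4.76 to -3.71 and M346 from -4.58 to -3.50. The mean correlation between groups, 0.77, was 0.74 with cyclic loess, 0.81 without a filter or with the floor from local background, 0.67 for features above the floor on all arrays, 0.69 with the floor from the N and B codes, and 0.74 to 0.77 with 1 array left out. The floor from local background kept all 406 features, so it was the same setting as no filter. The 195 features detected at 0 hour became 325 when 1 array sufficed. Scaling to control RNAs was not run, because the files name none, no choice of species was possible, and the run block is the replicate block. Features below about the floor have no reliable order, and M69 was limited by the scanner ceiling.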

Other observations

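The tests of slide position and of shared printing place were set before their results were seen, and the tests of scaling and of the difference between the same and different printing places after.

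Features with neighbouring codes changed alike. The 2 named features that fell belong to a stretch of 8 consecutive codes that all fell (limma, adjusted p under 0.05), with log2 fold changes between -2.85 and -4.45 and a median of -3.79. Over all tested features, the fold changes of codes 1 apart correlated with a Pearson r of 0.39 over 279 pairs (permutation p = 1e-04, the smallest that 10000 permutations can give; adjusted over 8 distances, 4e-04). The correlation was 0.31 at 2 codes apart, 0.19 at 3, 0.18 at 4, 0.14 at 5, 0.12 at 6, 0.07 at 7 and 0.11 at 8. Without the stretch of 8 it was 0.24 over 270 pairs (permutation p = 1e-04). Codes follow one another across the 4 blocks of the slide, so that nearly all codes 4 or 8 apart share a block, while codes 1 apart lie in different blocks. Codes 4 apart are thus close together, though not every such pair touches. An effect of position on the slide would make features close together in a block the more alike. The correlation of codes 1 apart exceeded that of codes 4 apart by 0.21 (95% bootstrap interval 0.04 to 0.35), which argues against position as the whole cause. This difference includes the stretch of 8 and was not taken without it, so part of it may rest on that stretch. A shared printing place would lower the correlation of consecutive codes at different places of their blocks to that of permuted codes, but it was 0.32 over 72 pairs (permutation p = 0.0028). That value also includes the stretch of 8 and was not taken without it, so what it says of a shared printing place may rest on the stretch. At the same place the correlation was 0.44 over 207 pairs, higher by 0.13 (95% bootstrap interval -0.17 to 0.37). Whether a shared printing place adds to the likeness therefore cannot be told apart from no such effect. What also stays open is whether neighbouring codes are probes of similar sequence that hybridise to one another's targets, or microRNAs that are made together. Either would make neighbouring codes change alike, and these cannot be told apart without the probe sequences. A candidate explanation is that the code order follows families or clusters of microRNAs.

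More features rose than fell in the main comparison (86 against 59). The choice of scaling may account for this excess, because the share of higher features among the called ones ranged from 24.5 to 68.0% over the 6 scalings. The 68.0% came without normalization between arrays, where the spread used by the test differed too. A real difference in the number of microRNAs made in each state was not tested, since no feature of known constant level was identified.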
